A study of Mus musculus with 11 samples.

How the data were processed

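Hi-C measures how often pairs of genomic sites lie close together: crosslinked chromatin is cut with a restriction enzyme, the ends are marked with biotin and ligated, and the junctions are sequenced. Per the labels, libraries were made from stimulated CH12 cells in 5 groups of 3 (shLacZ), 3 (shMcm), 2 (WT), 2 (C13_deltaori) and 1 (C13_KI) samples, 11 in all. The labels name the same set of processed files for every sample of a group, so the replicates were pooled before loops and domains were called. Per the submitters' processing notes, the genome build was mm9, and Trim Galore 0.6.2 and HOMER 4.10 were named without their role. The aligner and the settings of the callers are not given in the sources used here. The contact matrices and compartment tracks that the labels also name were not analysed here.

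Each group had 1 loop list and 1 domain list. The loop lists give 2 anchors of 5, 10 or 25 kb per loop and, in the last column, a p-value or q-value per loop that the authors deposited, all under 0.1; which of the possible q-values it is cannot be read from the lists, and the name of the lists points to the HiCCUPS caller. The domain lists give the start and end of each domain on a 5 kb grid and a score per domain that the authors deposited, with a lowest value of 1.5. Its definition and the domain caller are not given in the sources used here. Neither list holds read counts or an enrichment, so the depth behind each loop is unknown. A comparison of loop strength at shared loops was planned before the data were examined and could not be made from these lists. A deeper or sharper library yields more loops, more of them at 5 kb, and a pooled call hides the spread between replicates; both can move every loop count given here. For the same reason no test between conditions was possible, and each comparison was set beside the pair of control lists.

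Lists were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A loop was called found in another list where that list had a loop with both anchor midpoints within 25 kb. A boundary was a start or end of a domain, with those of 1 list within 5 kb of each other merged, and was called found within 20 kb. A domain was called shared at a reciprocal overlap of 80%. Shares carry Wilson 95% intervals and count ratios exact conditional binomial 95% intervals. Both cover counting error only, and loops of 1 list are not independent observations of a condition. Chance sharing came from 100 random shifts of every list within its chromosomes. Loop length is the distance between anchor midpoints, with intervals of the median from order statistics. Fisher's exact tests (two-sided) compared the loop counts of 2 lists per chromosome and per 2 Mb window, and the retained loops of a region with the rest of the genome, with Benjamini-Hochberg adjustment within each family. They compare lists, not conditions.

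The regions around Myc (chromosome 15, 61 to 63 Mb) and over Igh (chromosome 12) were fixed before the data were examined, from general knowledge of their place on mm9. The position of the deleted origin and of the knock-in is not stated in the labels. The share retained in a region was ranked among windows of the same width with at least 5 loops, with loops assigned to windows by their midpoint. Named features followed a fixed rule: the loops and domains of these regions, the 3 loops with the smallest q-value in 1 list of a comparison and not the other, in each direction, and the 3 chromosomes with the highest and lowest share of retained loops. The rule asked for the most enriched loops, and the q-value stood in for the enrichment. Several q-values are listed at 0, and ties were broken by position. Gene lists fixed beforehand were not run because an annotation of mm9 was not used here. A gene table of assembly GRCm38.p6 served only for the number of protein-coding genes per chromosome and for the order of neighbouring genes.

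The matching was tested on simulated data made from the shLacZ list. Of 6367 loops, 80.3% were kept and moved by 10 kb and 80.6% were found. Of 3223 boundaries, 79.4% were kept and moved by 15 kb and 81.0% were found. Of 1789 domains, 60.6% were shortened to 0.9 of their length, the others far more, and 60.6% were found. Each of these moves or cuts lay within the matching limit, so kept items were bound to be found. The counts show only how rarely replaced items matched. In the window test, 1 window was emptied in each of 20 simulations per size. It was called in 20 of 20 simulations for windows of at least 20 loops (drawn from only 4 such windows), and in 3 of 20 for 10 to 19 loops, and 0 other windows were called. A window needed 10 loops over both lists together, so that one of 5 to 9 loops was not tested once emptied. Alternatives covered the matching distance, a stricter q-value, equal list sizes, autosomes alone, a minimum domain length and the overlap of domains. The removal of loops with 5 kb anchors was added after the data were seen.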

Results

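Chromosome conformation capture with sequencing (Hi-C) was performed in CH12 cells, a mouse B-cell lymphoma line that switches antibody class in culture, grown with IL-4, CD40 and TGF-β stimulation. The 11 samples fall into 5 groups. The shLacZ group (n = 3) carried a control hairpin against a bacterial gene, and the shMcm group (n = 3) a hairpin against Mcm, the helicase family loaded at replication origins. Which Mcm member was targeted is not stated in the labels. The WT group (n = 2) was unmodified, C13_deltaori (n = 2) was the clone C13 with an origin deletion, and C13_KI (n = 1) carried a knock-in in that clone. As known of the published study, the origin lies at Myc and Igh is the translocation partner of Myc. Each group was represented by 1 pooled loop list and 1 pooled domain list, so no spread between replicates could be computed. Every interval given here covers counting error only. Read depth per sample is unknown from these lists. The yardstick for each comparison was therefore the pair of control lists, WT and shLacZ. These 2 lists also differ by the hairpin and in the number of pooled samples (2 in WT, 3 in shLacZ). Their difference is therefore not the spread between like lists. Whether the groups differ by batch was not examined. Positions are on the mouse build mm9.

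The 5 loop lists held between 4749 loops (shMcm) and 6367 loops (shLacZ), with 5584 in WT, 4887 in C13_deltaori and 5890 in C13_KI. A common set of loops and boundaries was present throughout: 2311 of the WT loops (41.4%) and 1996 of the WT domain boundaries (71.1%) were found in all 4 other lists. The median loop spanned 260 kb in WT (95% interval 250 to 270), 210 kb in shLacZ (200 to 225), 220 kb in C13_deltaori (210 to 225), 200 kb in shMcm (200 to 210) and 200 kb in C13_KI (195 to 200). Loops over 1 Mb made up 7.04% of the WT list (Wilson 95% interval 6.40 to 7.74) and 3.56% to 4.71% of the others. Domain lists held 1542 domains in WT, 1789 in shLacZ, 1901 in shMcm, 1667 in C13_deltaori and 1639 in C13_KI, with medians from 365 kb (shLacZ) to 420 kb (WT).

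**Figure D1:**
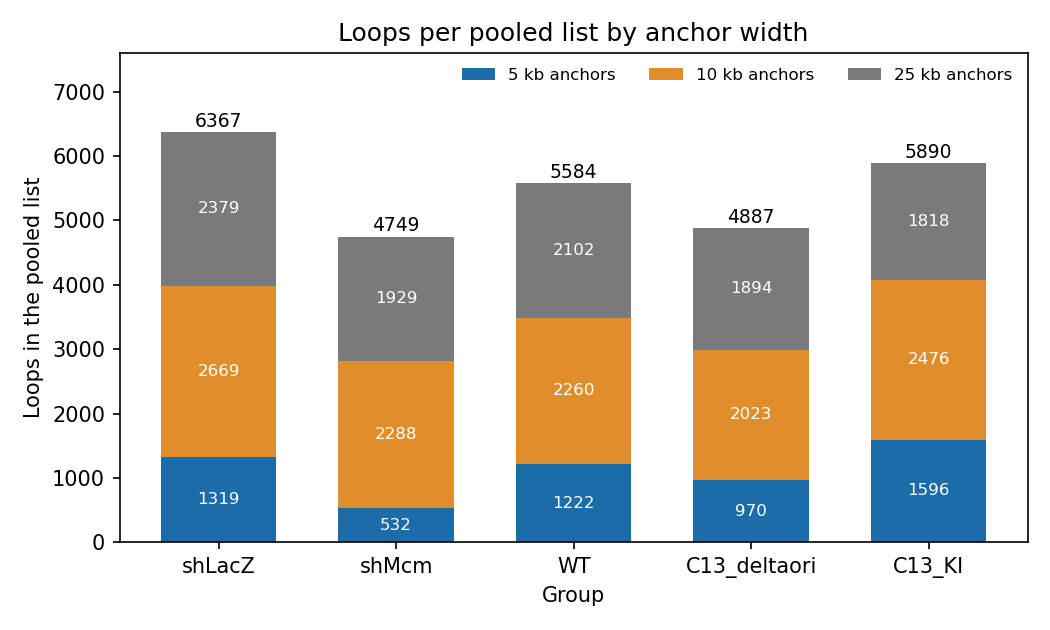
Number of loops in each pooled list (y axis) for the 5 groups (x axis), stacked by the width of the loop anchors. The shMcm list is the shortest, with 4749 loops, and holds 532 loops with 5 kb anchors against 970 to 1596 in the other lists.

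The control lists themselves differed. The shLacZ list held 1.14 times as many loops as WT (95% interval 1.10 to 1.18), with more loops on 19 of 20 chromosomes, and 1.16 times as many domains (1.08 to 1.24), with more on 20 of 20. Loops were shorter in shLacZ on all 20 chromosomes by the median. Of the WT loops, 73.5% were found in shLacZ (72.3 to 74.6), and of the shLacZ loops 64.7% were found in WT (63.6 to 65.9). Domain boundaries were found more often, at 89.7% of WT boundaries (88.6 to 90.8) and 78.6% of shLacZ boundaries (77.2 to 80). Loops shifted at random within their chromosome were found in 0.770% to 1.20% of cases on average, and shifted boundaries in 4.12% to 5.14%.

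**Figure D2:**
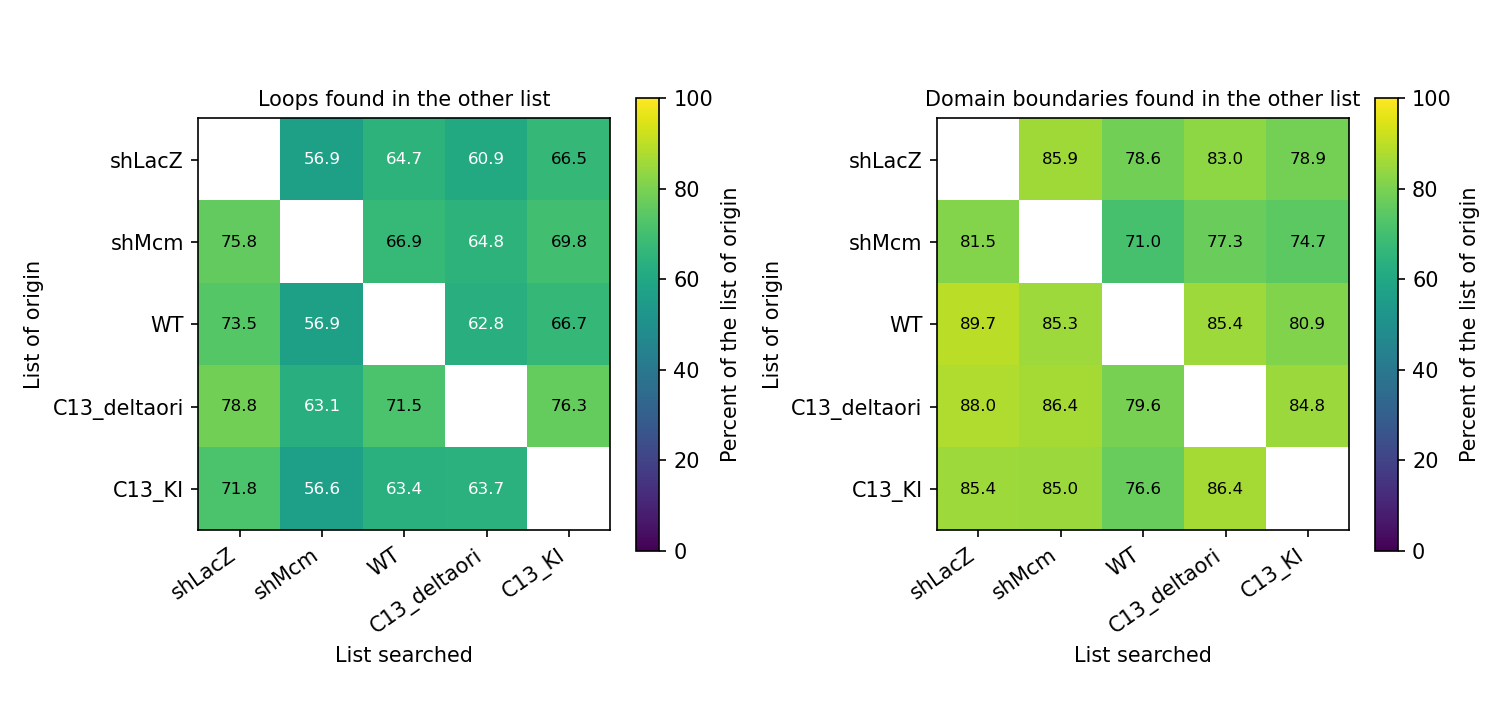
Percent of loops (left) and of domain boundaries (right) of each list of origin (y axis) that were found in the list searched (x axis), for all pairs of the 5 lists. Boundaries were found more often than loops in each pair, as in WT against shLacZ (89.7% of boundaries, 73.5% of loops).

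The comparison of shMcm with shLacZ asks how chromosome folding looks in cells with a hairpin against Mcm, whose level was not measured here. The shMcm list had fewer loops on each of the 20 chromosomes, at 0.746 times the shLacZ count (95% interval 0.718 to 0.775). The shortfall was deepest on chromosomes 17 and 4, at ratios of 0.651 and 0.652, and mildest on the X chromosome, at 0.853. No single chromosome stood out: in Fisher's exact tests against the other chromosomes, 0 of 20 had an unadjusted p under 0.05. Domains were not fewer: the shMcm list held 1.06 times the shLacZ count (0.996 to 1.13), with more on 14 chromosomes and fewer on 6. The domains of shMcm covered 998 Mb against 922 Mb in shLacZ.

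Of the shLacZ loops, 56.9% (55.7 to 58.1) had a counterpart in shMcm, and 75.8% (74.5 to 77.0) of the shMcm loops had one in shLacZ. Chromosome 18 (63.5%), chromosome 14 (63.3%) and chromosome 6 (61.2%) retained the largest share of shLacZ loops, and chromosome 19 (49.7%), chromosome 17 (50%) and chromosome 4 (50.8%) the smallest. Domain boundaries were retained at 85.9% (84.6 to 87.0), below the 89.7% of WT boundaries found in shLacZ but above the 78.6% of shLacZ boundaries found in WT. Of the 2743 shLacZ loops without a counterpart in shMcm, 43.8% (41.9 to 45.6) were present in WT. Long loops were retained less often: 42.7% (37.0 to 48.5) of shLacZ loops of 1 Mb or more against 59.5% (57.7 to 61.3) of those under 200 kb. The control pair of WT loops found in shLacZ declined further, from 81.9% to 46.9%. Against WT the order was the other way round, with 68.1% of the long and 61.3% of the short shLacZ loops found. The WT list held 393 loops over 1 Mb and the shMcm list 169, so a loss particular to the knockdown cannot be read from this order. The loop with the smallest q-value in shLacZ alone joined 88.05 to 88.075 Mb with 88.675 to 88.7 Mb of chromosome 11, and it was also present in WT and C13_KI. Another joined 81 to 81.025 Mb with 81.5 to 81.525 Mb of chromosome 13, and the last joined 8.675 to 8.7 Mb with 8.85 to 8.875 Mb of chromosome 16. Both were also present in WT and in each C13 list. Of these 3, the chromosome 16 loop alone had no shMcm loop within 50 kb. The 3 such loops of shMcm lay on chromosomes 19, 2 and 6, and each had a shLacZ loop within 50 kb.

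The ratio of shMcm to shLacZ differed by resolution, at 0.403 for loops with 5 kb anchors (0.364 to 0.446), 0.857 for 10 kb anchors and 0.811 for 25 kb anchors. These ratios count calls at each anchor width and do not show that the 5 kb sites were lost. Matched to shMcm loops of any anchor width, 78.0% of shLacZ loops with 5 kb anchors were found, 57.9% with 10 kb and 44.1% with 25 kb. In WT the order was the same, at 83.0%, 64.4% and 54.9%. With the same number of most significant loops taken from each list, the shares found became 59.2% for shLacZ in shMcm and 59.3% for WT in shLacZ, a difference under counting error. With full lists the order depended on direction: 56.9% of shLacZ loops were found in shMcm and 64.7% in WT, while 75.8% of shMcm loops and 73.5% of WT loops were found in shLacZ.

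The comparison of C13_deltaori with WT asks what the origin deletion clone shows genome-wide and at Myc. The clone had fewer loops on all 20 chromosomes, at 0.875 times the WT count (95% interval 0.842 to 0.910), and 1.08 times as many domains (1.01 to 1.16), with more on 19 chromosomes. Chromosome 16 was lowest, with 154 loops against 236 in WT, a ratio of 0.653, and chromosome 2 was highest at 0.953. Loops were shorter in the clone on all 20 chromosomes by the median.

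Of the WT loops, 62.8% (61.5 to 64.1) were found in C13_deltaori, against the 73.5% found in shLacZ. With the same number of most significant loops taken from each list this order turned, with 63.1% (61.7 to 64.4) found in C13_deltaori and 59.3% (57.9 to 60.7) in shLacZ, while the stricter list searched in the full other list kept it (64.3% against 74.6%). Chromosome 14 (71.6%), chromosome 7 (68.7%) and chromosome 6 (67.3%) retained most, and chromosome 16 (52.1%), the X chromosome (56.4%) and chromosome 4 (56.5%) least. Retention declined with length, from 70.6% (68.6 to 72.5) of WT loops under 200 kb to 41.3% (36.6 to 46.1) of those of 1 Mb or more. The WT loops found in shLacZ showed a similar decline, from 81.9% to 46.9%. Boundaries were retained at 85.4% (84.0 to 86.7) and domains at 82.9% (80.9 to 84.7). Of the 2077 WT loops absent from C13_deltaori, 33.3% (31.3 to 35.3) were present in C13_KI and 44.9% (42.7 to 47.0) in shLacZ. Among the 3 loops with the smallest q-values in WT alone, those at 32.025 to 32.3 Mb and 75.15 to 75.375 Mb of chromosome 14 had a C13_deltaori loop within 50 kb. The loop from 83.925 to 84.475 Mb of chromosome 15 had none and was also seen in shLacZ and shMcm. In the clone alone, loops at 22.75 to 22.875 Mb of chromosome 11 and 181.125 to 181.25 Mb of chromosome 2 had no WT loop within 50 kb. Both were also present in shLacZ, shMcm and C13_KI. The other lay at 27.675 to 27.8 Mb of chromosome 15.

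The knock-in list was set against WT and against the clone it derives from. C13_KI held 1.05 times the WT loop count (95% interval 1.02 to 1.09) and 1.21 times that of C13_deltaori (1.16 to 1.25), with more loops than C13_deltaori on all 20 chromosomes. Chromosome 16 stood apart again, with 174 loops against 236 in WT, a ratio of 0.737, when 16 chromosomes had more loops in C13_KI than in WT. Against the other chromosomes, the odds ratio of chromosome 16 was 0.690 for C13_KI over WT (Fisher's exact test, two-sided p = 0.000283, Benjamini-Hochberg 0.00565 over 20 chromosomes). It was 0.737 for C13_deltaori over WT (Fisher's exact p = 0.00376, adjusted 0.0751). No other chromosome passed the adjusted threshold of 0.05 in any of the 5 comparisons, and these tests compare lists, not conditions.

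**Figure D3:**
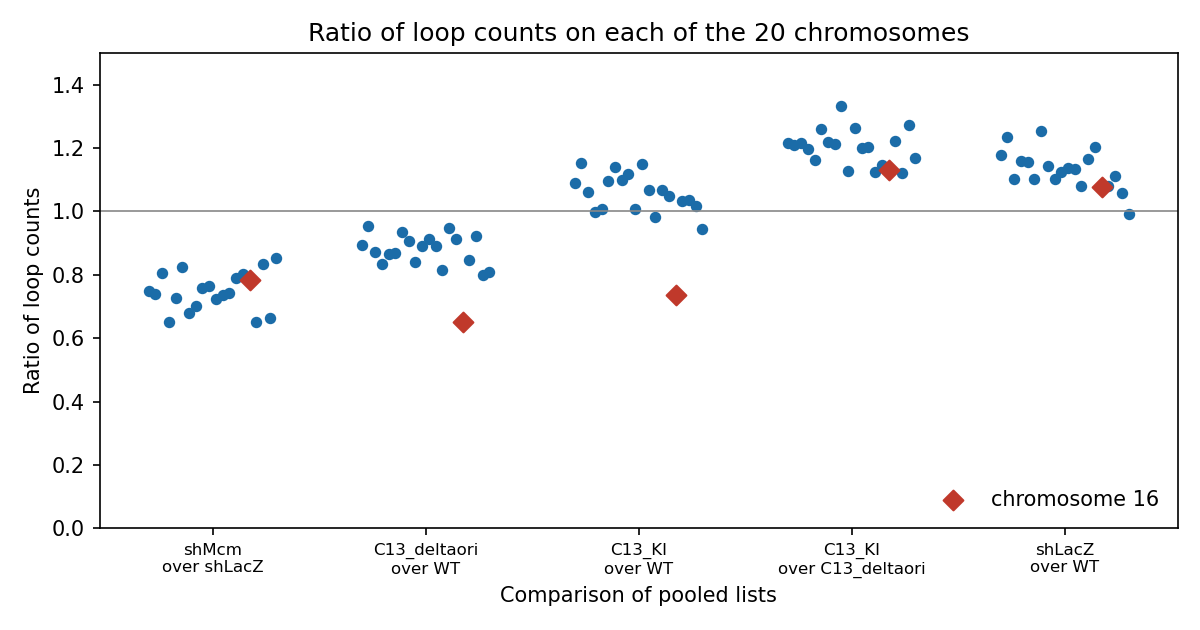
Ratio of loop counts (y axis) on each of the 20 chromosomes for 5 comparisons of pooled lists (x axis), ordered from chromosome 1 to X within each comparison, with chromosome 16 as a diamond. Chromosome 16 lies at 0.653 and 0.737 in the comparisons of the C13 lists with WT, below all other chromosomes, and within the range of the others elsewhere.

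Of the C13_deltaori loops, 76.3% (75.1 to 77.5) were found in C13_KI, and 66.7% (65.4 to 67.9) of the WT loops were. The latter share lay above the 62.8% of WT loops found in C13_deltaori, but this order depended on list length. With the same number of most significant loops from each list it turned. WT loops were then found at 57.1% (55.7 to 58.5) in C13_KI and 63.1% (61.7 to 64.4) in C13_deltaori. Chromosomes 11, 9 and 7 kept 81.0%, 80.2% and 80.1% of their C13_deltaori loops in C13_KI, and chromosomes 8, X and 10 kept 69.95%, 70.8% and 72.3%. From WT to C13_KI, chromosomes 7, 2 and 14 kept 73.6%, 72.2% and 70.8%, and chromosomes 16, X and 13 kept 53.0%, 60% and 62.9%. Boundaries were shared at 84.8% (83.4 to 86.0) between C13_deltaori and C13_KI and at 80.9% (79.4 to 82.3) between WT and C13_KI. Domain counts of C13_KI were 0.983 times those of C13_deltaori (0.918 to 1.05) and 1.06 times those of WT (0.991 to 1.14). WT loops of 1 Mb or more were found in C13_KI in 35.1% of cases (30.7 to 39.9), against 78.5% (76.7 to 80.2) of those under 200 kb. Named by smallest q-value, a loop from 58.775 to 59.05 Mb of chromosome 15 was absent from C13_KI and present in the 4 other lists, and a loop from 10.725 to 11.05 Mb of chromosome 19 was absent from C13_deltaori alone. A pair joining 53.95 to 53.955 Mb with 108.87 to 108.875 Mb of chromosome 11 was likewise absent from C13_KI alone. Of the 12 listings named for these comparisons, 9 had a loop of the other list within 50 kb, among them the chromosome 16 loop from 95.825 to 96.2 Mb, found in C13_KI and shMcm.

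The excess over WT depended on resolution. C13_KI had 1.31 times the WT count of loops with 5 kb anchors (1.21 to 1.41) but 0.865 times for 25 kb anchors (0.812 to 0.921). Without the 5 kb loops the ratio to WT was 0.984 (0.944 to 1.03), on the other side of 1 but with an interval that includes 1.

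**Figure D4:**
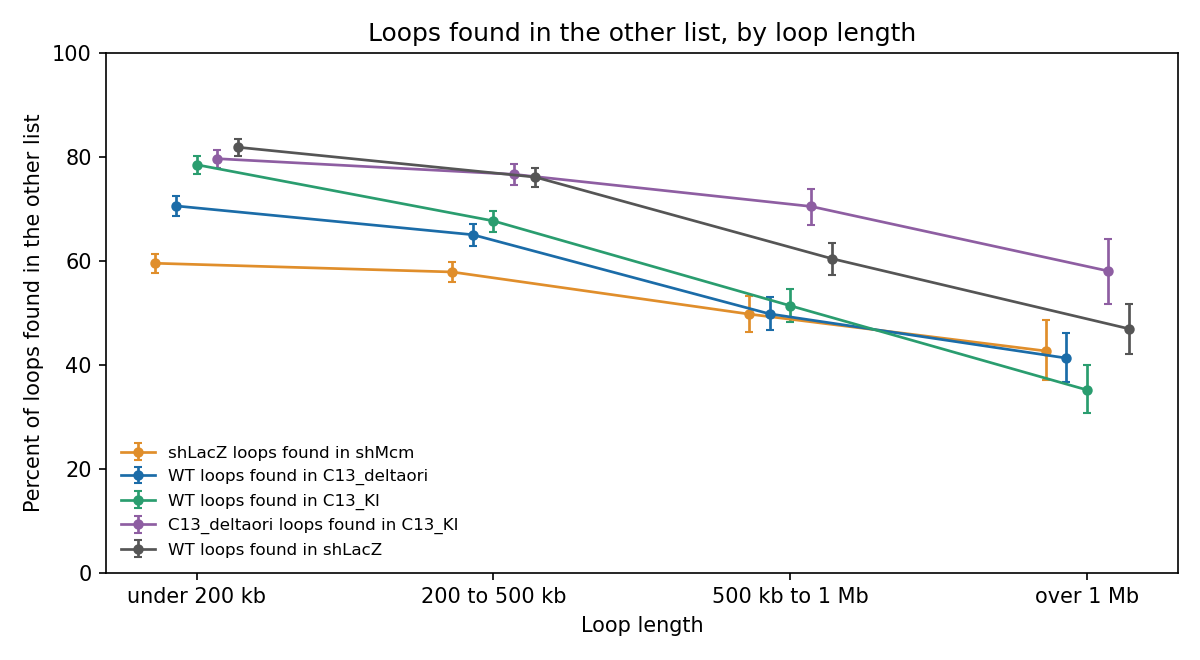
Percent of loops found in the other list (y axis) by loop length (x axis) for 5 pairs of lists, with Wilson 95% intervals as bars. Each of the 5 lines declines from the shortest to the longest loops, the control pair from 81.9% to 46.9%.

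At Myc, the oncogene that translocations join to Igh in mouse B-lineage tumours, the domain structure was the same in the 5 lists within 20 kb. One domain ended and the next began at 61.8 to 61.805 Mb of chromosome 15, within 25 kb of the gene, which lies near 61.82 Mb on mm9 by general knowledge. The domain on the far side reached 62.655 to 62.66 Mb and the near one started at 61.205 to 61.22 Mb. All 3 boundaries between 61 and 63 Mb were shared in each comparison at the limit of 20 kb. Within 10 kb, 2 of the 3 WT boundaries were found in C13_deltaori, and all 3 were shared in the other comparisons. Loops joining 61.23 to 61.25 Mb with 61.81 to 61.82 Mb, and 61.81 to 61.83 Mb with 62.63 to 62.64 Mb, were also present in all 5 lists. These span the upstream and downstream domains with Myc at the shared end.

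Loop content inside these domains varied. The 2 Mb region held 10 loops in shLacZ, 8 in shMcm, 7 in WT, 4 in C13_deltaori and 9 in C13_KI, of which 5, 5, 4, 2 and 3 had an anchor at Myc (61.8 to 61.83 Mb). In shMcm, 8 of the 10 shLacZ loops were found (80%, against 56.9% in the rest of the genome). In C13_deltaori, 2 of the 7 WT loops were found (28.6%, against 62.8%). Counted by loop midpoint, so that loops reaching out of the region enter, 3 of 11 WT loops were found in C13_deltaori, and 15 of 531 windows of the same width had a share as low or lower (2.82 percentile). Of the C13_deltaori loops, 2 of 5 by midpoint were found in C13_KI (2.17 percentile), and 3 of 5 with anchors within 50 kb (14.97 percentile), so that 1 loop moves this rank. In C13_KI, 5 of the 7 WT loops were found, and in shLacZ 6 of the 7. Loops from 62 to 62.025 Mb to 62.625 to 62.65 Mb, and from 62.09 to 62.12 Mb to 62.63 to 62.64 Mb, downstream of Myc towards its neighbour Pvt1 and beyond, were present in shLacZ, shMcm, WT and C13_KI and absent from C13_deltaori. The loop across both domains, from 61.225 to 61.25 Mb to 62.625 to 62.65 Mb, was present in shLacZ, WT and C13_KI. The loop from 61.365 to 61.38 Mb to 61.81 to 61.82 Mb was present in shLacZ, shMcm and WT and in neither C13 list. Other loops followed neither order. The loop from 61.24 to 61.25 Mb to 61.37 to 61.38 Mb was present in shLacZ, shMcm and C13_deltaori and absent from WT and C13_KI. A loop from Myc to 62.095 to 62.12 Mb was present in shLacZ, shMcm and C13_KI and absent from both WT and C13_deltaori. One loop of C13_deltaori, from 61.225 to 61.25 Mb to 61.975 to 62 Mb, was found in no other list. Loops found in no other list also occurred in shLacZ, shMcm, WT and C13_KI.

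With so few loops, none of these differences passed a test. Fisher's exact test of the region against the rest of the genome gave p = 0.110 for WT loops in C13_deltaori and p = 0.204 for shLacZ loops in shMcm, each 0.80 after Benjamini-Hochberg adjustment over 10 tests. With both anchors required within 10 kb the region ranked at the 10.4 percentile for WT loops in C13_deltaori and the 16.5 percentile for C13_deltaori loops in C13_KI.

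**Figure D5:**
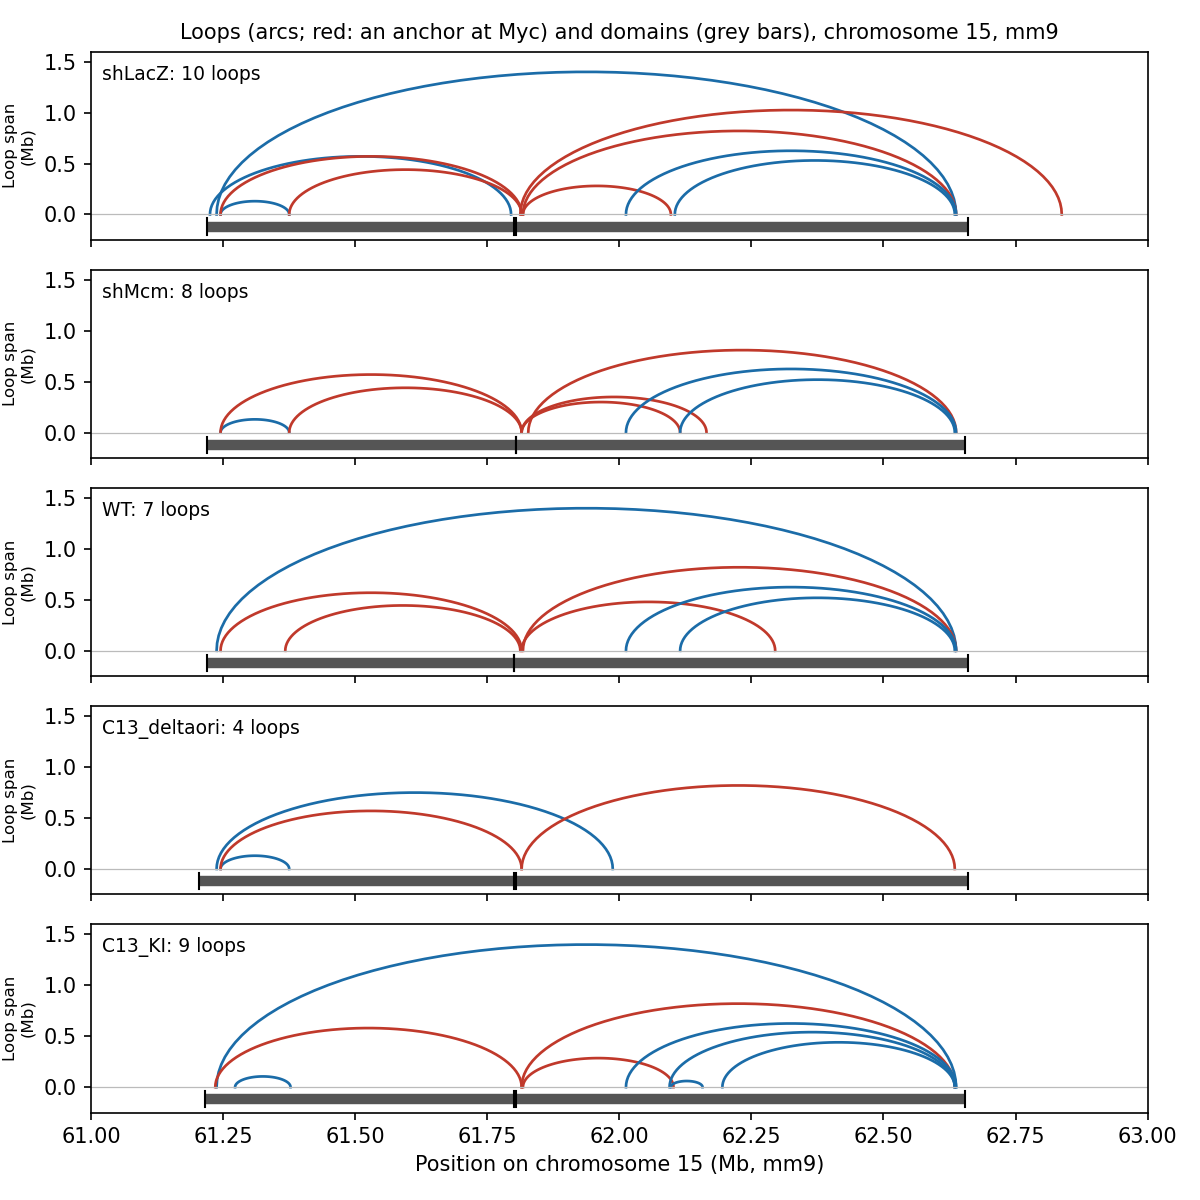
Loops as arcs (height: span in Mb, y axis) and domains as grey bars with black end ticks along chromosome 15 from 61 to 63 Mb (x axis, mm9) in the 5 pooled lists, with loops anchored at Myc in red. The domains meet at 61.8 to 61.805 Mb in every list, and C13_deltaori shows 4 loops against 7 in WT and 9 in C13_KI.

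At Igh, the immunoglobulin heavy chain locus on chromosome 12, a loop of 375 to 390 kb from 114.45 Mb to about 114.83 Mb was present in all 5 lists. A loop across the locus, from 114.45 to 114.475 Mb to 116.425 to 116.45 Mb in 3 lists and 10 kb wide in shLacZ, was present in shLacZ, shMcm, C13_deltaori and C13_KI and absent from WT. A short loop of 35 kb between 114.46 and 114.5 Mb was present in WT and C13_KI. The region held 3 loops in shLacZ, 2 in shMcm, 2 in WT, 2 in C13_deltaori and 4 in C13_KI. A 475 kb loop to 114.925 to 114.95 Mb was found in C13_KI alone, and a 2100 kb loop to 116.55 to 116.575 Mb in shLacZ alone. No list placed a domain inside the locus. A domain starting at 117.27 to 117.275 Mb bordered it in shLacZ, shMcm and C13_KI, and one ending at 114.44 Mb in shLacZ. Each of the 5 comparisons here rests on 2 or 3 loops, and no difference was detectable.

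Loops were also set against the domains of the same list. Both anchors lay within 25 kb of a boundary for 11.8% of loops in WT (11.0 to 12.7), 14.1% in shLacZ (13.3 to 14.98), 16.7% in shMcm (15.6 to 17.8), 13.8% in C13_deltaori (12.9 to 14.8) and 12.4% in C13_KI (11.6 to 13.3). A loop joined both ends of 38.9% of domains in shLacZ (36.7 to 41.2), 34.2% in shMcm (32.1 to 36.4), 32.7% in WT (30.5 to 35.1), 32.9% in C13_deltaori (30.7 to 35.2) and 36.4% in C13_KI (34.1 to 38.8). The share with both anchors at a boundary lay above both controls in shMcm. That list also held the most boundaries (3484, against 3223 in shLacZ and 2807 in WT), and no chance level was computed for this share. Loops with both anchors at a boundary numbered 792 in shMcm, 898 in shLacZ and 661 in WT. The share of domains with a loop joining both ends lay between the WT and shLacZ controls in the 3 other lists at 25 kb. At 10 kb it did not in shMcm (7.63% against 7.55% in shLacZ) and C13_deltaori (5.40% against 5.45% in WT), differences within counting error.

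Across the genome, loop counts were also compared in windows of 2 Mb holding at least 10 loops over both lists together. Of the 511 windows tested for shMcm against shLacZ, 0 passed a Benjamini-Hochberg adjusted Fisher's exact test and 1 had an unadjusted p under 0.05. The counts were 0 and 1 of 478 for C13_deltaori against WT, 0 and 0 of 515 for C13_KI against WT, 0 and 0 of 488 for C13_KI against C13_deltaori, and 0 and 0 of 553 for the control pair. On simulated lists, a window of 10 to 19 shLacZ loops emptied completely was called in 3 of 20 cases, and one of 5 to 9 loops falls under the minimum once emptied and was not tested, so that losses within most single windows were not detectable.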

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

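The alternatives were chosen before the data were examined, except the removal of loops with 5 kb anchors, which was chosen after the result was seen. Of 132 alternative values, 76 stayed within the 95% interval of the value reported, 55 left it and 1 crossed to the other side of 1. The cause was not tested unless the setting itself gives it. Leaving out a replicate was not run because only pooled lists exist. No paired analysis was possible because the lists carry no replicate numbers. Loop strength could not be computed from these lists, and the unknown depth limits every loop count. The 10 domain count alternatives, the autosome-only loop counts and lengths and the counts of loops and boundaries found at Myc and Igh stayed within their intervals. For Myc and Igh this says little, because the counts are small and their intervals wide (4.90 to 9.43 for the 8 shLacZ loops found in shMcm at Myc). At 10 kb, that count fell from 8 to 6, and the WT boundaries found in C13_deltaori at Myc from 3 to 2.

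Without 5 kb loops the loop count ratio was 0.835 for shMcm over shLacZ and 1.10 for C13_KI over C13_deltaori. For C13_KI over WT it was 0.984 (0.944 to 1.03), on the other side of 1 but with an interval that includes 1. Keeping the loops with the smallest 75% of q-values gave median lengths of 225 kb in shMcm, 290 kb in WT, 230 kb in C13_deltaori and 210 kb in C13_KI.

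For the share of loops found (shLacZ in shMcm, WT in C13_deltaori, WT in C13_KI, C13_deltaori in C13_KI, WT in shLacZ), a limit of 10 kb gave 42.9%, 48.4%, 51.7%, 60.1% and 56.8%, and 50 kb gave 60.2%, 65.6%, 70.1%, 79.3% and 76.5%. With 4749 loops from each list, the shares in this order were 59.2%, 63.1%, 57.1%, 64.7% and 59.3%. WT loops were then found more often in C13_deltaori than in shLacZ or in C13_KI, the reverse of the order with full lists and at 10 and 50 kb. The stricter list searched in the full other list gave 59.2% for shLacZ in shMcm, 64.3% for WT in C13_deltaori, 77.7% for C13_deltaori in C13_KI and 74.6% for WT in shLacZ, which kept the order of the full lists. The gap between loops under 200 kb and those of 1 Mb or more was 23.1 percentage points for shLacZ in shMcm at 10 kb.

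For boundaries, in the same order of pairs, 10 kb gave 81.7%, 82.1%, 76.3%, 81.6% and 86.3%, and 40 kb gave 87.8%, 87.2%, 83.3%, 86.5% and 91.6%. With 2807 boundaries drawn from each list the shares were 71.3%, 79.9%, 76.9%, 80.6% and 79.5%, lower because drawing removes partners at random. Domains at 90% overlap were shared at 79.7%, 80.2%, 73.6%, 81.0% and 85.9%, and at 70% overlap 79.1% of WT domains were found in C13_KI.

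With 10 kb in place of 25 kb, both anchors lay at a boundary for 2.51% (shLacZ), 3.58% (shMcm), 1.86% (WT), 2.17% (C13_deltaori) and 2.26% (C13_KI) of loops, and 7.55%, 7.63%, 5.45%, 5.40% and 6.59% of domains had a loop joining their ends. Anchors of 25 kb are coarser than this limit.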

Other observations

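The tests in this part were chosen after the results were seen, except the test of the least significant calls. Pairs of sites over 10 Mb apart formed 38 clusters over the 5 lists, of which 12 were present in every list. Outside chromosome 15, a pair joining 23.01 Mb with 39.98 Mb of chromosome 17 was present once in each of the 5 lists, and pairs joining 7.05 to 7.28 Mb and 8.575 to 8.6 Mb with 132.3 Mb of chromosome 3 were also present in all 5. On chromosome 11, sites at 87.225 to 87.28 Mb and 101.475 to 101.525 Mb were paired in each list. Of the 4 clusters in all 5 lists outside chromosome 15, 3 held 1 pair in every list and 0 held over 1 pair in every list. That is the pattern predicted for reads placed wrongly from single repeated bins, so these clusters cannot be told apart from such reads. A cluster joining 85.62 to 85.68 Mb with 125.95 to 125.96 Mb of chromosome 8 was present in both C13 lists, with 2 pairs in each, and in none of the WT, shLacZ and shMcm lists. On the X chromosome, 3 clusters were seen in WT alone. This was not particular to the X chromosome, since clusters in WT alone also lay on other chromosomes, such as chromosome 3. The WT list held the most pairs over 10 Mb apart, 41 against 25 to 33 in the other lists.

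Chromosome 16 held fewer loops in both C13 lists, with 154 in C13_deltaori and 174 in C13_KI against 236 in WT and 254 in shLacZ. An excess in the WT list alone is argued against by the odds ratios against shLacZ, 0.783 (95% interval 0.639 to 0.960) for C13_deltaori, 0.733 (0.602 to 0.891) for C13_KI and 0.755 for both summed, which count shared loops more than once. A loss in part of the chromosome is argued against because 4 of its 4 equal parts held a lower ratio, from 0.660 to 0.687, than the other chromosomes at 0.912. Fewer copies of chromosome 16 in the clone, which could lower the reads behind loops along its length, stays open: coverage was not analysed here, and the domain count ratio was 0.969 on chromosome 16 and 0.993 elsewhere. The origin deletion itself was not told apart from clonal origin, since both C13 lists come from 1 clone.

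Chromosome 15, which carries Myc, held 13 of the 38 long-range clusters. Of these, 7 joined sites near 3.15 to 3.275 Mb, 62.75 to 62.9 Mb (downstream of Myc) and 96.35 to 96.55 Mb with each other, or sites near 11.2 Mb and 13 Mb with 88.175 to 88.5 Mb and 93.82 to 94.05 Mb, and 1 further cluster in all 5 lists joined 59.47 to 59.675 Mb with 89.55 to 89.85 Mb. Something that arose with the knockdown or in the C13 clone is argued against, since 61.5% of the clusters were present in all 5 lists, WT included. Reads placed wrongly from single repeated bins are argued against for 5 of those 8 shared clusters (62.5%), which held over 1 pair in every list. Misplaced reads from a repeated stretch wider than 1 bin could also give several pairs in every list, so this count cannot exclude them. A rearranged chromosome 15 in the cell line, with these sites close together on the derived chromosome, could give such clusters and was left open by the 8 clusters seen in all 5 lists, because coverage and reads across a join were not analysed here.

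The ratio of shMcm to shLacZ loops was lower on chromosomes with more protein-coding genes per Mb (Spearman rho -0.70, permutation p = 0.00076, Benjamini-Hochberg 0.0038 over 5 comparisons). Pearson r was -0.67 (permutation p = 0.00112, adjusted 0.0056). Without the 2 chromosomes most distant from the median gene density, rho was -0.645 and r was -0.71. The 20 chromosomes are not replicates. Such a trend was not found with the knockdown only: rho was -0.57 (adjusted p = 0.0223, permutation) for C13_deltaori over C13_KI, the lowest of the 4 other comparisons. C13_deltaori over WT (rho 0.03), WT over C13_KI (rho -0.34) and WT over shLacZ (rho -0.18) did not pass. Without 5 kb loops rho was -0.51 for C13_deltaori over C13_KI (95% bootstrap interval -0.81 to -0.07, adjusted p = 0.119, permutation). A trend in that pair, in which C13_KI was 1 sample, cannot decide whether the knockdown contributes to the trend in shMcm. A loss of the least significant calls, as with less sensitive calling, may contribute: keeping only as many of the most significant shLacZ loops as shMcm has gave rho -0.51 (95% bootstrap interval -0.84 to -0.02) within 1 list. Whether loops with 5 kb anchors carry the trend cannot be told apart from chance, with rho -0.43 (-0.78 to 0.02, adjusted p = 0.146, permutation) without them. A change of loops in gene-dense chromosomes under reduced Mcm stays open and was not tested apart from list length.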
